A study of Mus musculus with 8 samples.

How the data were processed

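Gene expression was measured by CAGE in tissue around a cortical aspiration cavity from mice killed immediately after the lesion (4 samples) or 1 week after it (4 samples). Per the labels' protocols, total RNA was extracted with a column kit and the CAGE libraries were sequenced as single-end reads of 75 nt on a NextSeq 500. Per the submitters' processing notes, BWA 0.5.9 and the mouse build mm9 were used. The rules by which tags were assigned to genes, including the use of strand, are not given in the sources used here. The deposited table holds 1 CPM value (tags scaled to a common library total) for each of 17644 gene symbols and 8 columns. No coordinates are given, since the reference at hand (GENCODE M21 on GRCm38) is another build than mm9. Gene start positions from a reference served only to tell which genes neighbour each other.

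Column names show the group and a 6-base tag followed by a 3-base tag, but no replicate number, so each column was assigned to its group and not to one numbered sample. The 3-base tag is CAC in all no-delay columns and GCT in all 1-week columns, and the same 6-base tags occur once in each group. No column was left out. The labels give separate samples in each group, and where nothing says that each came from its own animal, p-values measure only the spread between these samples. Within each group the libraries differed by more than counting noise (mean chi-square per degree of freedom from 8.36 to 15.9 and median from 1.19 to 2.63 over genes with at least 20 reads), which does not by itself show that they are separate samples. They were counted as separate because the labels list them so.

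The deposited CPM values are whole multiples of the value of 1 read, so reads could be recovered: 100% of values came out whole within 0.1 reads, and the libraries held 8278855 to 13998941 reads. A count of 3 reads, the upper limit that 0 observed reads allow, corresponds to 0.214 to 0.362 CPM. Intervals on ratios of reads are 95% and cover counting error only, since tags without molecular identifiers are not independent molecules. Reads counted for more than one gene were found as rows with the same reads in every library: 194 genes in 95 sets, and none of the named genes was among them. Among neighbouring genes, 55 pairs had reads within 5% of each other in every library, and many of these pairs are also in those sets.

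The main test was limma 3.58.1 (R 4.3.3) with a variance trend on log2(CPM + 1) for the 14718 genes with a CPM of 1 or more in at least 4 libraries; the other 2926 genes were not tested. A gene below 1 CPM in all no-delay libraries passed this filter only with 1 CPM or more in all 4 1-week libraries. The test was 2-sided, p-values were adjusted by Benjamini-Hochberg, and genes with adjusted p under 0.05 were called. Fold changes are 1 week over no delay and lie on the log2(CPM + 1) scale, which understates the change of genes with few reads. Means, SDs and ratios of means were taken from CPM. For Grn an exact 2-sided permutation test over the 70 arrangements was added. The tests named in this paragraph with their thresholds, the 30 gene lists and the rule for naming genes were fixed in advance.

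The genes named were Grn, Psap, Sort1 and Tmem106b; the 8 genes with the highest and the 8 with the lowest log2 fold change among called genes with a mean CPM of 5 or more and no overlap between the groups, passing over symbols that are only gene models; and, for each list, up to 3 called members with the largest absolute log2 fold change, or the member with the highest mean CPM where none was called. This gave 88 genes, of which a few are not reported here. Of 451 list entries, 428 matched a symbol in the table, 2 of them through synonyms in the reference and 2 through aliases written with the lists (Sc4mol for Msmo1 and C1s for C1s1). Lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over 27 lists.

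The procedure was tested on simulated reads with the no-delay means, the depths of this comparison and 200 changed genes. The changed genes had a no-delay mean of 5 CPM or more, so recovery of genes with fewer reads was not tested. They were raised and lowered in near equal numbers, unlike the calls with CPM as deposited. Of the genes changed 1.5-fold, limma recovered 76.1% (51 of 67), and of those changed 2-fold and 4-fold it recovered 98.5% and 100%, with 13 false calls among 14172 unchanged genes (14372 tested). EdgeR 4.0.16 recovered 73.1% of the 1.5-fold changes with 14 false calls, and DESeq2 1.42.0 recovered 80.6% with 18. Camera called the changed list and 0 of 30 unchanged lists. The simulated genes were drawn independently of each other, and only 200 were changed. The simulation therefore does not show how often camera at its preset correlation calls unchanged lists whose genes are correlated.

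The alternatives fixed in advance were other pseudocounts (0.25 and 5), no filter and a CPM filter of 5, scaling by TMM factors, by median-of-ratios factors and by quantiles, limma without a trend, robust or with library weights, each library left out in turn, other thresholds, and, on the recovered reads, the quasi-likelihood test of edgeR 4.0.16 (2923 genes higher, 2567 lower) and DESeq2 1.42.0 (2799 higher, 2762 lower). Added after seeing the data were CPM without mitochondrial, hemoglobin and Malat1 reads, a block on the shared 6-base tag, and a correction for GC content and length of GENCODE M21 transcripts, matched by symbol for 97.2% of tested genes (98.3% of those called higher and 96.9% of those called lower). A planned block on replicate number was not run, because the columns carry no such number.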

Results

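CAGE (cap analysis of gene expression), which counts sequencing tags from the capped 5' ends of RNA, was used to measure gene expression in mouse brain tissue around a surgical cavity. The cavity was made in the motor cortex of 11-week-old male C57BL/6NCrSlc mice by aspiration, and the tissue within 1.0 mm of it was collected. In 4 samples the brain was taken immediately after the lesion (no delay), and in 4 it was taken 1 week later. The series title concerns progranulin and the survival of grafted human stem cell-derived neurons, so the comparison asks how the host tissue, and progranulin (Grn) in it, differed between a fresh cavity and one that was 1 week old. Libraries are named by group and by the short tag in their column name. The libraries held 8278855 to 13998941 reads assigned to genes. The lowest depth was in the 1-week library tagged acagtg and the highest in the 1-week library tagged cgatgt.

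The 8 libraries separated by group. The first principal component carried 72.2% of the variance of log2(CPM + 1) and placed all no-delay libraries on one side and all 1-week libraries on the other, while the second carried 6.40%. Pearson correlations across genes, which are not independent replicates, were 0.989 to 0.991 within the no-delay group, 0.986 to 0.990 within the 1-week group and 0.945 to 0.968 between the groups. Hemoglobin transcripts took 0.0652% to 0.154% of reads in the no-delay libraries and 0.0344% to 0.530% in the 1-week libraries. Mitochondrial gene symbols, some of which count the same reads more than once, made up 2.995% to 5.38% of CPM without delay (mean 4.13%) and 2.40% to 3.05% at 1 week (mean 2.70%).

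Progranulin, a secreted growth factor that also acts in lysosomes, was higher at 1 week. Grn stood at 45.2 CPM ± 0.940 (SD, n = 4) without delay and at 244 CPM ± 58.4 (SD, n = 4) at 1 week, a ratio of means of 5.41. The no-delay libraries lay between 44.2 and 46.1 CPM, and the 1-week libraries between 190 CPM (tagged tgacca) and 325 CPM (tagged atcacg). The log2 fold change on the log2(CPM + 1) scale was 2.38 (SE 0.13, 95% interval 2.10 to 2.66, limma adjusted p = 7.2e-08). The exact 2-sided permutation test over the 70 arrangements of the libraries gave p = 0.0286, the smallest that 4 against 4 allows. Among the genes tested, Grn ranked 103 by log2 fold change and 44 by p.

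Of 3 genes chosen in advance because their products act with progranulin, 1 was higher, 1 was lower and 1 was not called, with log2 fold changes closer to 0 than that of Grn. Psap, the precursor of the saposins that binds progranulin, stood at 893 CPM ± 81.3 (SD, n = 4) without delay and 1074 CPM ± 116 (SD, n = 4) at 1 week, with a log2 fold change of 0.26 (SE 0.09, limma adjusted p = 0.0443). Sort1, the sortilin receptor that takes up progranulin, fell from 323 CPM ± 14.5 to 279 CPM ± 20.7, with a log2 fold change of -0.21 (SE 0.07, limma adjusted p = 0.0271). Tmem106b, a lysosomal membrane protein, stood at 187 CPM ± 8.72 and 186 CPM ± 7.11 (SD, n = 4 each, limma adjusted p = 0.931). The Psap call did not hold without any one of the no-delay libraries tagged atcacg, cgatgt or tgacca or the 1-week libraries tagged acagtg, atcacg or cgatgt, with adjusted p from 0.0701 to 0.138, nor with TMM scaling (adjusted p = 0.107); 14 of 23 alternatives ended it (adjusted p from 0.0142 to 0.138 over all of them). The Sort1 call was lost without the no-delay library tagged acagtg (adjusted p = 0.0679) and without the 1-week libraries tagged acagtg, atcacg or cgatgt (adjusted p from 0.0510 to 0.0915), and in 7 of 23 alternatives in all (adjusted p from 8.2e-04 to 0.102 over all of them).

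**Figure D1:**
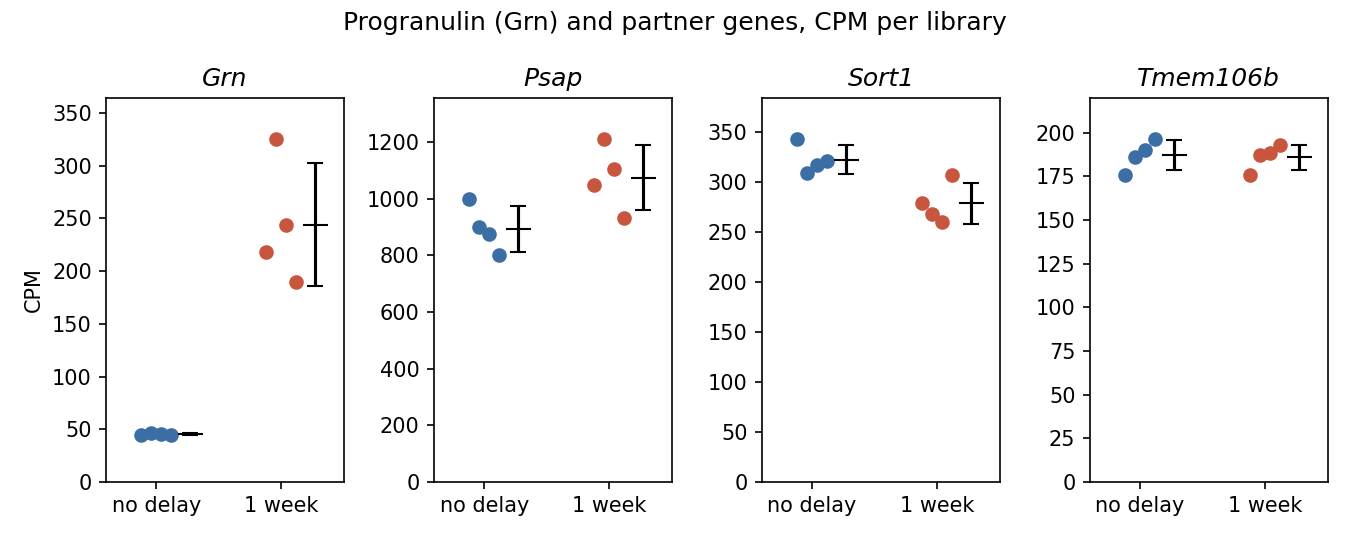
CPM of Grn, Psap, Sort1 and Tmem106b in each of the 8 libraries (points, 4 per group, no-delay and 1-week groups on the x axis) with the group mean and SD (black bars), each panel with its own y axis from 0. The 1-week libraries lie at 190 to 325 CPM for Grn, above the no-delay libraries at 44.2 to 46.1 CPM.

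Over the whole transcriptome the tissue changed widely after 1 week. Of the 14718 genes tested, 3439 were higher and 1971 were lower at 1 week (limma, Benjamini-Hochberg adjusted p under 0.05), and 9308 were not called. Large changes were nearly all increases: 927 of the genes called higher and 56 of those called lower had an absolute log2 fold change of 1 or more. Gfap, the intermediate filament of astrocytes, went from 31.4 CPM ± 5.02 to 1174 CPM ± 288 (SD, n = 4 each), a ratio of means of 37.4 and a log2 fold change of 5.16 (SE 0.16, limma adjusted p = 3.3e-09). Cxcl10, an interferon-induced chemokine, went from 0.333 to 38.3 CPM, Spp1, which encodes osteopontin, from 3.07 to 138 CPM ± 129 (SD), and Lyz2, the lysozyme of macrophages, from 5.50 to 162 CPM. Ifi27l2a, an interferon-induced gene, rose from 5.97 to 153 CPM, complement C4b from 3.53 to 86.3 CPM, the apolipoprotein gene Apoc1 from 1.28 to 40.4 CPM, and A2m, a protease inhibitor, from 1.08 to 35.8 CPM. The 1-week mean of Spp1 is 74.8 CPM without the library tagged atcacg (329 CPM), and the no-delay mean of Cxcl10 is 0.06 CPM without the library tagged tgacca (1.15 CPM).

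The genes that fell most fell by smaller factors, with -2.05 as the strongest log2 fold change among all called genes. Those named here are the ones that the naming rule picked. Nhlrc1, which encodes the ubiquitin ligase malin, fell from 22.3 CPM ± 2.13 to 7.94 CPM ± 2.04 (SD, n = 4 each; log2 fold change -1.41, SE 0.15, limma adjusted p = 1.8e-05). Bsn, a scaffold protein of the presynaptic active zone, fell from 363 CPM ± 186 to 136 CPM ± 26.2 (SD, n = 4 each). Its no-delay value was 631 CPM in the library tagged atcacg and 225 to 342 CPM in the others. The activity-regulated transcription factor gene Egr4 fell from 73.2 to 31.3 CPM, and the kinase gene Sik1 from 22.1 to 9.10 CPM. Cds1, an enzyme of phospholipid synthesis, fell from 131 to 54.5 CPM, the translation initiation factor gene Eif3b from 86.0 to 36.2 CPM, and the dynein light chain gene Dynll2 from 1307 to 546 CPM. In 3345 genes every 1-week library lay above every no-delay library and in 1763 every one lay below, together 34.7% of the genes tested, where chance gives 2.86%. The balance of higher to lower depended on the scaling: 63.6% of the called genes were higher with CPM as deposited, 52.1% with TMM scaling, 50.9% with median-of-ratios scaling and 43.4% with quantile normalization, which moved the median log2 fold change of all genes from 0.06 to -0.04.

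**Figure D2:**
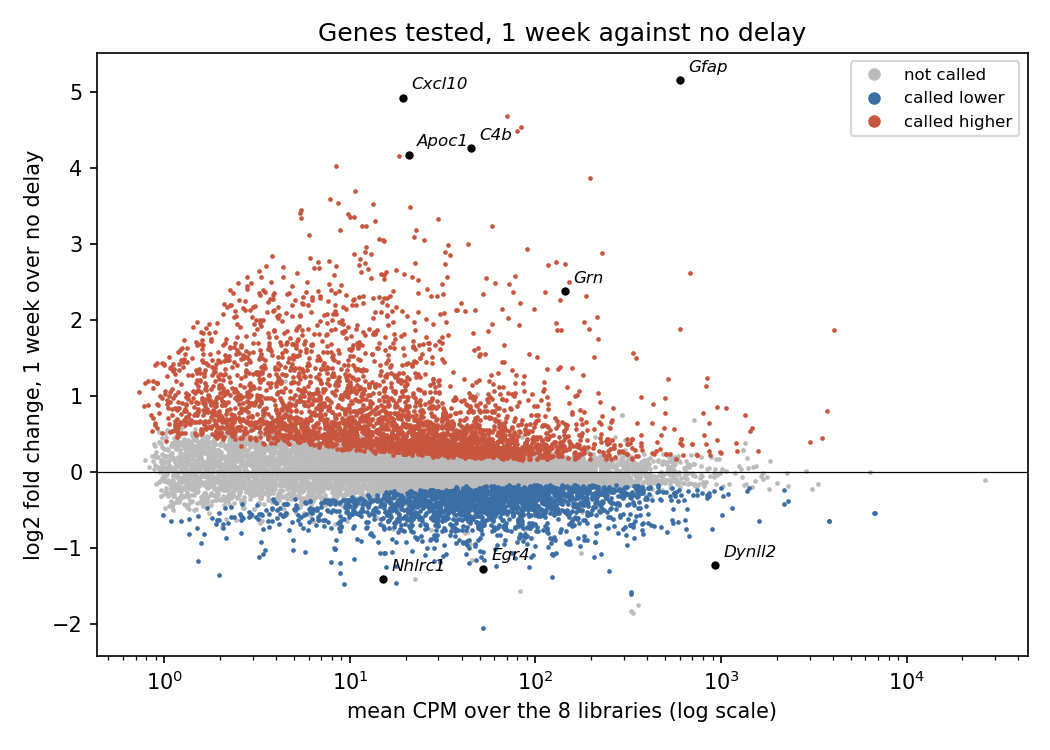
Log2 fold change at 1 week over no delay (y axis, log2(CPM + 1) scale) against mean CPM over the 8 libraries (x axis, log scale) for each of the 14718 genes tested, coloured by limma call (adjusted p under 0.05), with 8 named genes in black. The 3439 genes called higher reach log2 fold changes of up to 5.16 (Gfap), while the named gene with the strongest decrease, Nhlrc1, lies at -1.41.

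Microglial genes rose as a whole, those of resting cells as well as those of phagocytic cells. All 12 tested genes of the homeostatic microglia list were higher, 12 also when adjusted over the list alone, with a median log2 fold change of 1.63. Fcrls went from 23.6 CPM ± 3.85 to 128 CPM ± 34.4 (SD, n = 4 each), Olfml3 from 11.0 to 50.4 CPM, and the receptor gene Gpr34 from 9.62 to 41.9 CPM. All 19 tested genes of the phagocytic and disease-associated microglia list were higher, 19 also when adjusted over the list alone, with a median of 2.40. Besides Spp1, the galectin gene Lgals3 went from 0.285 CPM (0.167 CPM without the no-delay library tagged atcacg) to 15.3 CPM. Cst7, a cystatin, had 2 reads over the 4 no-delay libraries and 840 over the 4 1-week libraries (no-delay mean 0.0475 CPM, and 0.03 CPM without the library tagged acagtg), a pooled ratio of 353 with a 95% counting interval of 97.4 to 2918. Of 13 monocyte and macrophage genes in the table, 7 passed the filter. All 7 were higher, 7 also when adjusted over the list alone (median 2.00). Genes near 0 CPM without delay pass the filter only if they rose, so part of this unanimity may follow from it. Beside Lyz2, the Fc receptor gene Fcgr1 rose from 2.14 to 20.7 CPM and Ms4a7 from 0.640 to 9.71 CPM. Camera called the homeostatic (adjusted p = 1.0e-10), phagocytic (adjusted p = 1.4e-14) and monocyte (adjusted p = 1.2e-05) lists higher at its preset correlation. These calls were lost with an estimated correlation (adjusted p = 0.0619, 0.0988 and 0.0988 with an estimated correlation, in the same order).

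Lysosomal genes, the list that holds Grn itself, rose as well. Of its 25 genes, 21 were higher, 1 was lower (Sort1) and 3 were not called, against 22 higher and 1 lower when adjusted over the list alone, with a median log2 fold change of 0.99. Cathepsin S (Ctss), a protease of microglial lysosomes, went from 36.6 CPM ± 4.35 to 251 CPM ± 32.4 (SD, n = 4 each), and cathepsin D (Ctsd) from 179 CPM ± 10.9 to 1185 CPM ± 549. Camera gave adjusted p = 4.2e-11, and adjusted p = 0.112 with an estimated correlation. Of these 25 genes, Ctsb and Ctsd are also in the phagocytic list.

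Innate immune pathways rose together. All 13 tested complement genes were higher, 13 also when adjusted over the list alone (median log2 fold change 2.08). C1qa, a subunit of the initiating complex of the classical pathway, went from 52.9 CPM ± 3.45 to 405 CPM ± 96.4 (SD, n = 4 each), and the receptor gene C3ar1 from 1.25 to 25.3 CPM. Of 14 antigen presentation genes, 13 were higher and 1 was not called, and 14 were higher when adjusted over the list alone (median 2.07). The class I gene H2-K1 went from 32.0 to 225 CPM, the immunoproteasome gene Psmb8 from 5.54 to 37.8 CPM, and Cd74, the class II invariant chain, from 6.02 to 40.4 CPM. All 18 tested interferon-stimulated genes were higher, 18 also when adjusted over the list alone (median 2.66), among them Ifit3 (2.49 to 39.6 CPM) and Oasl2 (2.15 to 26.5 CPM). Of 15 cytokine and chemokine genes in the table, 9 passed the filter, which genes near 0 CPM without delay pass only if they rose. All 9 were higher, 9 also when adjusted over the list alone (median 2.45). Beside Cxcl10, the monocyte chemoattractant genes Ccl12 and Ccl2 rose from 0.635 to 20.6 CPM and from 0.180 to 6.93 CPM (Ccl2 stood at 0.1 CPM without the no-delay library tagged tgacca). The camera adjusted p was 1.2e-11 for complement, 2.8e-11 for antigen presentation, 2.5e-14 for interferon-stimulated genes and 3.2e-08 for cytokines, and adjusted p = 0.0619, 0.0988, 0.0988 and 0.0970 with an estimated correlation.

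Astrocyte genes rose in both of their lists. Of 14 reactive astrocyte genes, 13 were higher and 1 was not called, and 14 were higher when adjusted over the list alone, with a median log2 fold change of 1.86. Beside Gfap, vimentin (Vim) went from 23.8 CPM ± 3.53 to 369 CPM ± 93.4 (SD, n = 4 each) and the protease inhibitor gene Serpina3n from 7.54 to 62.0 CPM. All 13 homeostatic astrocyte genes were higher, 13 also when adjusted over the list alone, with a smaller median of 0.64. The water channel gene Aqp4 went from 23.8 to 109 CPM, the gap junction gene Gja1 from 108 to 308 CPM, and the potassium channel gene Kcnj10 from 63.9 to 167 CPM. Camera gave adjusted p = 4.0e-10 for the reactive and 1.3e-08 for the homeostatic list, and adjusted p = 0.0619 for each with an estimated correlation.

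Genes of proliferation, vessels and connective tissue were also higher. Of 16 cell cycle genes, 14 were higher and 2 were not called, also when adjusted over the list alone (median 1.31). Top2a, a topoisomerase of dividing cells, went from 0.450 to 5.56 CPM, Cdc20 from 0.815 to 7.02 CPM and Cdk1 from 0.313 CPM (0.203 CPM without the no-delay library tagged atcacg) to 4.43 CPM. Of 12 endothelial genes, 9 were higher and 3 were not called (9 when adjusted over the list alone, median 0.62), with the tight junction gene Cldn5 going from 36.01 to 81.7 CPM, the VEGF receptor gene Kdr from 7.55 to 17.7 CPM, and Cdh5 from 8.28 to 15.4 CPM. Of 13 fibroblast and matrix genes, 11 were higher and 2 were not called (11 when adjusted over the list alone, median 1.15). The matrix glycoprotein gene Sparc rose from 28.0 to 138 CPM, and the collagen genes Col3a1 and Col1a1 from 2.25 CPM ± 1.09 to 20.1 CPM ± 21.9 and from 7.31 CPM ± 2.51 to 37.2 CPM ± 26.5 (SD, n = 4 each). The 1-week library tagged atcacg had the highest Col3a1 value, 53.0 CPM, against 7.97 to 10.8 CPM in the other 1-week libraries, whose mean is 9.19 CPM. Of 11 pericyte and smooth muscle genes, 6 were higher and 5 were not called (8 when adjusted over the list alone, median 0.47), among them Notch3, Kcnj8 and Pdgfrb at log2 fold changes of 0.79, 0.67 and 0.52. Camera gave adjusted p = 3.2e-08 for the cell cycle, 8.0e-04 for endothelium, 1.8e-04 for fibroblasts and 0.0300 for pericytes, and adjusted p = 0.0619, 0.129, 0.184 and 0.321 with an estimated correlation. The pericyte call was also lost without the no-delay library tagged tgacca (adjusted p = 0.0506) or the 1-week library tagged tgacca (adjusted p = 0.0824), and with quantile normalization (adjusted p = 0.101), which ended the calls of Notch3 (adjusted p = 0.0552) and Kcnj8 (adjusted p = 0.197). A CPM filter of 5 (camera adjusted p = 0.0543) and library weights (camera adjusted p = 0.0648) ended the pericyte call too. The pericyte median was 0.16 with quantile normalization. Over all alternatives the adjusted p of the pericyte list ranged from 0.00305 to 0.321, that of Notch3 from 4.3e-04 to 0.0552 and that of Kcnj8 from 0.00675 to 0.197.

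Genes of the oligodendrocyte lineage were moderately higher. Of 10 precursor genes, 6 were higher and 4 were not called (6 when adjusted over the list alone, median log2 fold change 0.49). Gpr17, a receptor of committed precursors, went from 12.6 CPM ± 2.13 to 44.6 CPM ± 17.2 (SD, n = 4 each), the phosphatase gene Ptprz1 from 47.1 to 95.7 CPM, and the transcription factor gene Sox10 from 26.2 to 41.8 CPM. Of 12 oligodendrocyte and myelin genes, 7 were higher and 5 were not called (8 when adjusted over the list alone, median 0.60). Cldn11, a tight junction protein of myelin, rose from 42.1 to 86.4 CPM. Mbp, which encodes myelin basic protein, went from 1030.5 CPM ± 443 to 1679 CPM ± 405 with overlapping groups, and Mag, which encodes the myelin-associated glycoprotein, from 44.2 to 71.7 CPM. Camera gave adjusted p = 0.0155 for the precursor list and 0.0435 for the myelin list, and adjusted p = 0.213 and 0.611 with an estimated correlation. The myelin call was lost without any one of the no-delay libraries tagged atcacg, cgatgt and tgacca or the 1-week libraries tagged acagtg and atcacg (adjusted p from 0.0641 to 0.118) and with fry (adjusted p = 0.116), with adjusted p from 0.00162 to 0.611 over all alternatives. The Mbp call was lost in 10 of 23 alternatives (adjusted p from 0.00198 to 0.133 over all), among them each omission but those of the no-delay library tagged acagtg and the 1-week library tagged tgacca, where the lost calls had adjusted p from 0.0672 to 0.0902. The Mag call was lost in 8 of 23 (adjusted p from 0.00400 to 0.106 over all), among them the omission of the no-delay libraries tagged atcacg or tgacca or the 1-week libraries tagged acagtg, atcacg or cgatgt (adjusted p from 0.0653 to 0.0862).

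In 3 lists of neuronal genes most members were not called, and more of them were lower than higher. Of 13 general neuron genes, 4 were lower and 9 were not called, also when adjusted over the list alone, with a median log2 fold change of -0.14. Dlg4, which encodes the postsynaptic scaffold PSD-95, fell from 368 CPM ± 17.9 to 290.5 CPM ± 34.4 (SD, n = 4 each), the neuronal nuclear antigen gene Rbfox3 from 325 to 262 CPM, and synapsin gene Syn1 from 413 to 350.3 CPM, and the synaptotagmin gene Syt1, named after its value was seen, had a log2 fold change of -0.20. Of 14 glutamate and GABA receptor genes, 5 were lower and 9 were not called, also when adjusted over the list alone (median -0.09). This median was -0.157 with TMM scaling, -0.163 with median-of-ratios scaling and -0.051 with quantile normalization. The NMDA receptor gene Grin1 fell from 603 CPM ± 26.6 to 468 CPM ± 40.1 (SD, n = 4 each), and the AMPA receptor gene Gria3 from 324 to 259 CPM. Gria2 and Gabbr1, also lower, were named after their values were seen (log2 fold changes -0.27 and -0.31). Of 11 GABAergic neuron genes, 3 were lower, 1 was higher and 7 were not called, also when adjusted over the list alone (median -0.21). The neuropeptide genes Tac1 and Sst fell from 11.2 to 4.61 CPM and from 364 to 276 CPM, and Dlx1, named after its value was seen, had a log2 fold change of -0.37. Pvalb, which encodes the calcium-binding protein parvalbumin, rose from 53.6 to 94.6 CPM. Camera called these lists lower, with adjusted p = 0.0180 for general neurons, 0.00270 for receptors and 0.0379 for GABAergic neurons, and adjusted p = 0.209, 0.129 and 0.129 with an estimated correlation. Quantile normalization ended all of these calls (adjusted p = 0.228, 0.124 and 0.124). The general neuron call was lost without the 1-week library tagged tgacca (adjusted p = 0.0588), and the GABAergic call without the no-delay library tagged cgatgt (adjusted p = 0.0625), the no-delay library tagged tgacca (adjusted p = 0.0512) or the 1-week library tagged atcacg (adjusted p = 0.0604). Over all alternatives the adjusted p ranged from 0.00769 to 0.228 for general neurons, from 0.00101 to 0.129 for receptors and from 0.0199 to 0.129 for GABAergic neurons. The Syn1 call was lost without the no-delay libraries tagged acagtg or tgacca or the 1-week libraries tagged atcacg or tgacca (adjusted p from 0.0503 to 0.0766, and from 0.00165 to 0.0889 over all alternatives).

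The glutamatergic neuron list was not called (camera adjusted p = 0.0635, and adjusted p = 0.141 with an estimated correlation). Of its 12 genes, 4 were lower, 2 were higher and 6 were not called, against 5 lower and 2 higher when adjusted over the list alone (median -0.13). The layer 5 transcription factor gene Fezf2 fell from 35.98 CPM ± 3.81 to 24.1 CPM ± 3.40 (SD, n = 4 each), and Neurod6 fell from 107 to 75.5 CPM. Rorb, a transcription factor of layer 4 neurons, rose from 75.0 to 109 CPM. Bcl11b and Grin2a (lower) and Cux2 (higher) were named after their values were seen, at log2 fold changes of -0.42, -0.19 and 0.32. Fry, which tests whether the genes of a list move one way without comparing them with other genes, gave adjusted p = 0.00217 for a decrease.

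Immediate early genes, which neurons and other cells induce within minutes of a stimulus, went both ways, with more of them lower than higher. Of 17 genes, 6 were lower, 3 were higher and 8 were not called, against 8 lower and 3 higher when adjusted over the list alone (median log2 fold change -0.67, camera adjusted p = 0.0115). Egr3 fell from 169 CPM ± 11.6 to 80.3 CPM ± 19.1 (SD, n = 4 each), beside Egr4. Without uninjured tissue, whether the no-delay values were already raised by the surgery cannot be told. Atf3, a transcription factor gene induced by injury, went from 0.375 to 6.09 CPM, and Jun and Btg2, named after their values were seen, had log2 fold changes of 0.54 and 0.70. The call was lost with an estimated correlation (adjusted p = 0.448 with an estimated correlation), with quantile normalization (adjusted p = 0.0855) and with fry (adjusted p = 0.401), and its adjusted p ranged from 0.00138 to 0.448 over all alternatives.

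Cholesterol synthesis genes fell together. Of 16 genes, 14 were lower and 2 were not called, also when adjusted over the list alone, with a median log2 fold change of -0.54. The sterol oxidase gene Sc4mol fell from 174 CPM ± 11.4 to 83.3 CPM ± 6.25 (SD, n = 4 each), and squalene synthase gene Fdft1 fell from 54.0 CPM ± 1.37 to 27.9 CPM ± 2.76. The list had a camera adjusted p = 5.8e-11, and adjusted p = 0.0988 with an estimated correlation.

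Secreted growth and trophic factors went both ways, with more of them higher. Of 32 tested genes, 16 were higher, 5 were lower and 11 were not called, also when adjusted over the list alone (median log2 fold change 0.52, camera adjusted p = 0.00300, and adjusted p = 0.0970 with an estimated correlation). The median was 0.46 with TMM scaling and 0.15 with quantile normalization. Grn and Spp1 are members and were among the highest. The ciliary neurotrophic factor gene Cntf had 3 reads over the no-delay libraries and 214 over the 1-week libraries, a pooled ratio of 59.9 with a 95% counting interval of 20.2 to 293. The 5 that fell, named after their values were seen, were Bdnf, Pdgfa, Fgf2, Vegfb and Vegfa, at log2 fold changes of -0.86, -0.64, -0.51, -0.38 and -0.36. Bdnf, the brain-derived neurotrophic factor, fell from 29.4 to 15.8 CPM.

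Among the lists that were not called, none of the 7 red blood cell genes passed the test (median log2 fold change 0.38, camera adjusted p = 0.891). Hbb-b1, a beta globin gene, varied widely, with 894 CPM ± 307 without delay and 1799 CPM ± 1829 at 1 week (SD, n = 4 each; 960 CPM at 1 week without the library tagged acagtg). None of the 16 oxidative phosphorylation genes, all of them nuclear, was called (median 0.12, camera adjusted p = 0.538), and Cox6a1 stood at 1803 and 1731 CPM. Of 11 heat shock genes, the co-chaperone gene Bag3 was higher (4.93 to 12.1 CPM), Hsp90aa1 was lower (313 to 267 CPM) and 9 were not called, also when adjusted over the list alone. The heat shock list's median of -0.04 and camera's direction (lower, adjusted p = 0.537) differed in sign from its mean of 0.08 and from fry's direction, and the median was 9.7e-04 with quantile normalization. Of 12 reference genes, 4 were higher and 8 were not called, also when adjusted over the list alone (median 0.07, camera adjusted p = 0.561), while fry called the list higher (adjusted p = 0.00579). The 4 were the lysosomal glucuronidase gene Gusb (14.2 to 47.1 CPM), the glycolytic gene Gapdh (148 to 199 CPM), the actin gene Actb (2596 to 3430 CPM) and Pgk1, named after its value was seen (log2 fold change 0.27). Actb was not called with quantile normalization (adjusted p = 0.0544; from 4.0e-04 to 0.0544 over all alternatives). Gusb is also in the lysosome list. With an estimated correlation these lists had adjusted p = 0.958, 0.858, 0.724 and 0.659, in the order given.

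Too few genes of the remaining 3 lists were tested for a list test. Of 7 neutrophil genes in the table, 2 passed the filter. Csf3r rose from 4.82 to 29.3 CPM and S100a8, named after its value was seen, was not called (limma adjusted p = 0.369). Of 11 lymphocyte genes in the table, only Cd79b passed the filter, and it rose from 0.428 to 1.95 CPM. Single genes such as Csf3r and Cd79b do not show that neutrophils or lymphocytes entered the tissue. Of 3 genes of choroid plexus and ependyma, the ciliary transcription factor gene Foxj1 rose from 0.770 to 3.23 CPM and 2 were not called.

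**Figure D3:**
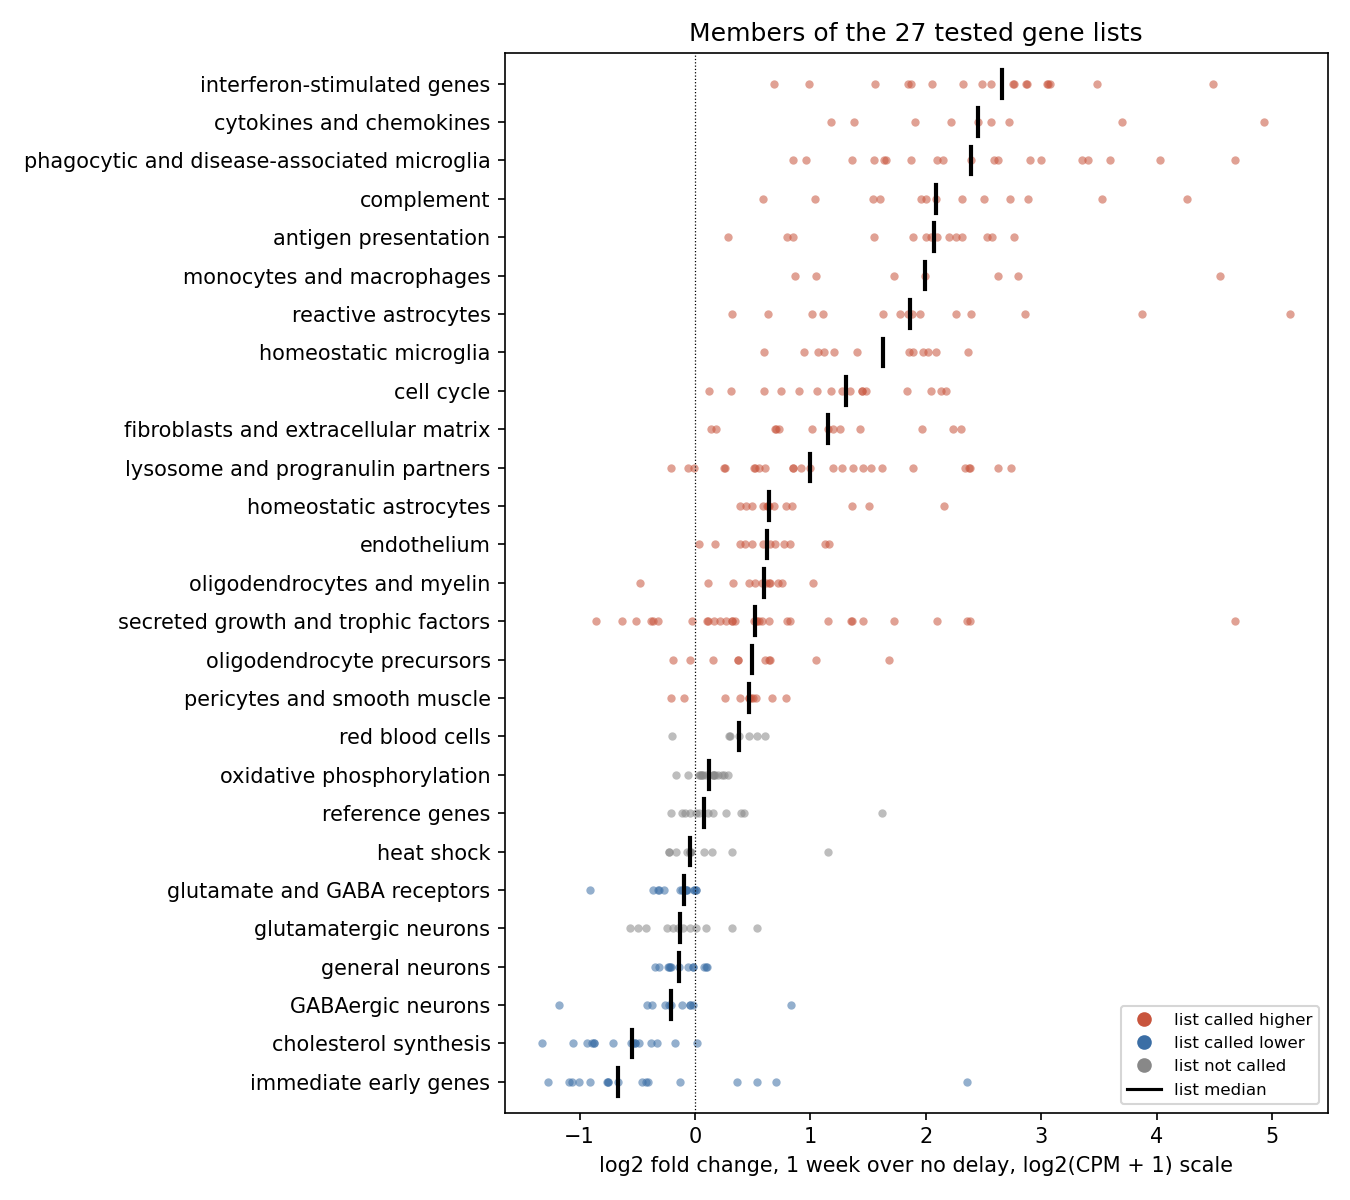
Log2 fold change at 1 week over no delay (x axis, log2(CPM + 1) scale) of each tested member (points) of the 27 tested gene lists (y axis), with the list median as a black line and colour by the camera call at the preset correlation. The 17 lists called higher have medians from 0.47 to 2.66 and the 5 called lower from -0.67 to -0.09, and with an estimated correlation none was called.

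Across the lists, camera at its preset correlation called 17 of 27 higher and 5 lower, and fry called 17 higher and 5 lower, though not the same ones: it did not call the myelin and immediate early gene lists, and called the reference genes higher and the glutamatergic list lower. With an estimated correlation it called 0, with the lowest adjusted p at 0.0619, and 12 of the lists had an unadjusted p under 0.05.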

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

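The counts over splits of the libraries were fixed before the data were examined; the tests of blood, the 3-base tag, dilution, GC content and length, microglia and shared reads were chosen only after the result was seen, and that of blood replaced 2 earlier ones, of which 1 rested on a lone library and 1 on a covariate that moved little. A library was singled out where its gap to the nearest of the other 3 of its group exceeded 0.829 of the group's range. This occurred in 20 of 238 sets of values, where chance alone gives about 1 in 20, or 11.9. The 1-week library tagged atcacg accounted for 7 of them, and no other library for more than 4.

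The 1-week library tagged atcacg was highest for Col3a1 (53.0 CPM, others 7.97 to 10.8), Ctsd (2003 CPM, others 854 to 1000), C1qa (548 CPM, others 336 to 371), Lgals3 (26.5 CPM, others 10.4 to 12.7), Ms4a7 (16.9 CPM, others 6.21 to 7.97) and the endothelium list mean (5.06 on the log2 scale, others 4.60 to 4.63), and lowest for Kcnj8 (4.80 CPM, others 5.56 to 5.70). The 1-week library tagged acagtg was highest for Ifi27l2a (289 CPM, others 94.7 to 122) and Sc4mol (92.7 CPM, others 79.4 to 81.0). The 1-week library tagged tgacca was lowest for C4b (68.1 CPM, others 90.9 to 94.0) and Hsp90aa1 (245 CPM, others 274 to 275), and the 1-week library tagged cgatgt was lowest for Apoc1 (22.3 CPM, others 44.6 to 47.6). Among no-delay libraries, the one tagged tgacca was highest for Cxcl10 (1.15 CPM, others 0 to 0.18) and lowest for Ptprz1 (27.1 CPM, others 51.2 to 55.9), the glutamatergic neuron list mean (7.12, others 7.18 to 7.19) and the cell cycle list mean (1.29, others 1.40 to 1.42). The one tagged acagtg was lowest for Ms4a7 (0.31 CPM, others 0.73 to 0.79) and Cntf (0 CPM, others 0.09 to 0.1), and the one tagged atcacg was lowest for Vim (18.6 CPM, others 25.3 to 26.0) and Col1a1 (3.57 CPM, others 8.23 to 8.91).

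The first pattern weighed is the rise of 3439 genes. Chance is argued against: 1 of the 35 splits of the libraries, the real one, gave as many, and the highest of the others gave 1. No smaller share is possible with 35 splits. The other splits place libraries of both groups in an arm, so few calls were to be foreseen in them. Red cells left in the tissue are argued against as the whole cause: the 2 1-week libraries with the least hemoglobin (0.0344% and 0.0777% of reads, against a no-delay mean of 0.111%), set alone against the no-delay libraries, had 82.9% of these genes called higher. The 3-base tag cannot be told apart from the delay, since 0 no-delay libraries carry the tag of the 1-week group. With that open, a response of the tissue over the week may account for the rise but was not separated from it.

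The second pattern is the fall of 1971 genes. Chance is argued against here to the same extent, with 1 of 35 splits giving as many and the highest other giving 1. The genes that rose took 12.8% of CPM without delay and 19.8% at 1 week. This forces a log2 shift of -0.12 on the summed CPM of the rest. Of the genes that fell, 69.2% had a 95% interval wholly below that shift, so it could not by itself account for their fall. The median log2 fold change of all tested genes was 0.06, so a typical gene was not shifted down. Scaling by TMM and by median-of-ratios factors gave 2664 and 2759 genes lower, more than with CPM as deposited. It moved the median of all tested genes down, to 8.9e-04 and -0.0054, so these added calls do not bear on dilution. The intervals and the median with CPM as deposited argue against dilution as the whole cause of the fall. GC content and length of the whole transcript are argued against as the whole cause. After a correction for them, 80.7% of these genes with a value stayed called lower. Their median log2 fold change was -0.40 before and -0.38 after. The GC content of the 5' ends that CAGE reads was not corrected for and stays open. A smaller share of neuronal RNA in the tissue and lower expression in the cells that remained both stay open, as does the 3-base tag. No uninjured tissue was sampled, so these falls are relative to tissue taken right after surgery and not to normal tissue.

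The third pattern is the rise of Grn. Reads shared in full or nearly so are argued against. No gene had the same reads as Grn, and 0 of the genes near it in genome order had reads within 5% of its own. Sharing of only part of the reads was not tested and stays open. More microglia at constant expression per cell stays open as a cause. The log2 fold change of Grn (2.38) lay 1.51 SD above the mean of the 12 homeostatic microglia genes (1.54, SD 0.55), although all 12 lay below it. These 12 genes ranged from 0.60 to 2.37, so their spread is wide and the test could hardly reject this cause. Higher expression in each cell, or expression in other cell types, was not tested and stays open, as does the 3-base tag.

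For the lists, 4 of the 35 splits called as many as the real 22 or more, with 23 as the highest other. Those that reached 22 besides the real one all keep 3 of the 4 1-week libraries together, and so still carry much of the group difference. They cannot decide whether chance gives a count of that size in camera at its preset correlation. The counts follow the structure of the samples: the 16 splits that keep 3 of the 4 1-week libraries together called 13 to 23 lists, and the 18 that keep 2 together called 1 to 6.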

How the results depend on the processing

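The correction for GC content and length, the block on the shared 6-base tag and the CPM without mitochondrial, hemoglobin and Malat1 reads were chosen after seeing the data. Grn kept its direction and its call under every alternative run, with log2 fold changes from 2.23 to 2.49. Of the other 87 named genes, 77 kept direction and call under all alternatives that gave a value (a CPM filter of 5 leaves out genes with few reads) and 10 did not: Psap, Sort1, Syn1, Mbp, Mag, Notch3, Kcnj8, Actb, Tmem106b and Hbb-b1. No gene called as reported was called in the opposite direction under any alternative. With each library left out in turn, genes higher ranged from 2841 to 3448, genes lower from 1429 to 2142, lists higher from 15 to 17 and lists lower from 4 to 5, and Grn from 2.23 to 2.49.

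Genes lower moved to 3211 with quantile normalization, where the median of all genes lies below 0, and the cause was not tested further. A threshold of adjusted p under 0.01 left 1093 genes lower, and an absolute log2 fold change of 1 or more left 927 higher and 56 lower, by construction. Lists lower moved to 1 with quantile normalization, and lists higher and lower to 0 and 0 with camera and an estimated correlation (12 at an unadjusted p under 0.05; fry called 17 and 5, with 2 lists lost and 2 gained), which is larger than the preset for most lists; the cause was not tested further.

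Some values that were not called changed sign. Tmem106b turned to 0.0375 with quantile normalization, 0.0895 with the GC correction, and 6.2e-04, 0.0155 and 0.0182 without the no-delay libraries tagged cgatgt and tgacca and the 1-week library tagged acagtg. Hbb-b1 turned to -0.16 with library weights and -0.28 without the 1-week library tagged acagtg. The red blood cell list turned lower with a pseudocount of 0.25 (adjusted p = 0.993), with library weights (0.523) and without the no-delay library tagged cgatgt (0.799) or the 1-week libraries tagged acagtg (0.476) and tgacca (0.739). Oxidative phosphorylation turned without the no-delay library tagged cgatgt (0.627) and with the GC correction (0.867), reference genes with the GC correction (0.960), and heat shock with fry (0.373). With each library left out in turn, Tmem106b ranged from -0.0378 to 0.0182, Hbb-b1 from -0.28 to 1.03, the adjusted p of the red blood cell list from 0.0908 to 0.956 and that of oxidative phosphorylation from 0.287 to 0.697. The cause was not tested.

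No paired analysis was possible because the columns carry no replicate numbers and no source used here ties libraries that share a sequence tag to each other, so the planned block on replicate number was not run. A block on the shared 6-base tag gave 3484 genes higher and 1986 lower. Libraries with the same tag did not all deviate together (correlations of deviations of -0.02, -0.03, 0.04 and 0.18), and best matched their own tag for cgatgt and tgacca only. Depth limits genes near 0.214 to 0.362 CPM, the limits that 0 reads allow.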

Other observations

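The gene families in this part and all of its tests were chosen only after the results were seen. In 4 families of genes for immune receptors, interferon-induced proteins and lipid carriers, all tested members were higher at 1 week; Fcgr1 and Apoe among them are also in the lists of the report. All 8 tested Toll-like receptor genes were called higher by limma (median log2 fold change 1.74), with Tlr2 going from 0.470 CPM ± 0.0762 to 16.7 CPM ± 6.13 (SD, n = 4 each) and Tlr3 from 7.92 to 21.4 CPM. All 6 Fc receptor genes were higher (median 2.48), with Fcer1g going from 21.03 to 123 CPM and the inhibitory receptor gene Fcgr2b from 2.55 to 28.2 CPM. All 6 guanylate-binding protein genes, which are induced by interferon, were higher (median 2.08), led by Gbp6 at 1.34 and 22.0 CPM. Of the apolipoprotein genes, Apoc2 and Apoc4, at 0 CPM without delay, could pass the filter only by rising. All 5 tested apolipoprotein genes were higher (a family narrowed after a first symbol pattern had taken in unrelated genes). Among them were the abundant lipid carrier gene Apoe (1737 to 6398 CPM) and Apod (45.8 to 224 CPM). In camera, adjusted over 9 families (that of ribosomal proteins is not used here, because its symbol pattern took in other genes), these had adjusted p = 1.3e-06, 4.9e-07, 5.5e-06 and 4.6e-06 in this order, and adjusted p = 0.0884, 0.0884, 0.110 and 0.0510 with an estimated correlation. Their medians stayed above 0 with TMM, median-of-ratios and quantile scaling.

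Among genes of neuronal excitability and peptide release, more were lower than higher. Of 69 tested potassium channel genes, 30 were lower, 8 were higher and 31 were not called by limma (median log2 fold change -0.23). The 2-pore channel gene Kcnk2 fell from 39.8 CPM ± 8.94 to 16.8 CPM ± 2.28 (SD, n = 4 each), while Kcnj10, which astrocytes express, was among those that rose. Kcnj10 and Kcnj8 are also in the lists of the report. Of 19 genes with voltage-gated calcium channel symbols, gamma subunits included, 9 were lower, 1 was higher (Cacng5) and 9 were not called (median -0.23). Of 18 neuropeptide and granin genes, 7 were lower, 1 was higher (Chga) and 10 were not called (median -0.28). Penk, which encodes enkephalins, fell from 42.7 to 18.6 CPM, Vgf from 149 CPM ± 6.29 to 85.7 CPM ± 8.33, and Adcyap1 from 19.95 to 9.30 CPM; Sst, Tac1, Npy and Vip of this family are also in the GABAergic list, and Cacng4 is in the oligodendrocyte precursor list. Camera gave adjusted p = 5.9e-06, 3.2e-04 and 9.0e-05, and adjusted p = 0.110, 0.183 and 0.147 with an estimated correlation. These medians stayed below 0 with TMM, median-of-ratios and quantile scaling.

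Within each library, the mean of the phagocytic microglia list was set against that of the homeostatic list. A change in the number of microglia alone would leave their difference in place only if the genes of both lists came from microglia alone. That premise was not tested, and the pseudocount of 1 also compresses changes of genes with few reads. The difference of the means was -0.81 ± 0.05 (SD, n = 4) without delay and 0.11 ± 0.31 at 1 week on the log2 scale, a shift of 0.92 present in 4 of 4 libraries (exact permutation p = 0.0286, adjusted p = 0.0429 over 3 such tests; 95% interval over the members of the lists 0.32 to 1.51). On that premise only, more microglia at constant expression per cell is argued against as the whole cause of the rise of both lists. As a hypothesis, a change of state, or cells of another kind such as macrophages, may account for the difference. For astrocytes the reactive list shifted against the homeostatic list by 1.19 (exact permutation p = 0.0286, adjusted p = 0.0429, 4 of 4 libraries; 95% interval over members 0.41 to 1.97), from -4.42 ± 0.16 to -3.22 ± 0.16 (SD, n = 4 each). If the genes of both lists came from astrocytes alone, this argues in the same way against more astrocytes at constant expression per cell as the whole cause. That premise was not tested, so expression of genes of either list in other cell types stays open. The glutamatergic list shifted against the GABAergic list by 0.0819 (95% interval -0.04 to 0.21, exact permutation p = 0.229, 3 of 4 libraries above all no-delay libraries). A loss of one neuron class more than the other stays open, since members of both lists went both ways (SD of their log2 fold changes 0.32 and 0.47).

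Some values belong to single libraries or tags. Ttr, a transcript of the choroid plexus, stood at 104 CPM in the no-delay library tagged atcacg and at 0 to 0.2 CPM in the others. Mt-Nd4 stood at 21 CPM in the 1-week library tagged cgatgt and at 207 to 663 CPM elsewhere, and mt-Atp6 at 26.8 CPM in the no-delay library tagged atcacg and at 117 to 719 CPM elsewhere. Of 15 mitochondrial genes for proteins and ribosomal RNAs, 8 were lower and 7 were not called by limma (median log2 fold change -0.63). With the tRNA symbols, 36 in all, camera gave adjusted p = 8.8e-08, and adjusted p = 0.147 with an estimated correlation; several of these symbols have nearly the reads of a neighbour, and 4 share all their reads with another gene, so the test counts some reads more than once. With the shared 6-base tag as a term, 3 genes differed between tags in limma at adjusted p under 0.05 (1080 at unadjusted p under 0.05): Hbs1l and Gm14325, highest in both libraries tagged atcacg (28.5 and 36.7 CPM against 5.05 to 7.29 for Hbs1l), and Ndufb4, lowest in those tagged atcacg and cgatgt (23.4 to 30.5 CPM against 130 to 337).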
